A study of Mus musculus with 9 samples.

How the data were processed

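RNA from mouse CD4 T cells was hybridised to whole-genome Affymetrix mouse expression arrays, 9 in all. The labels put 3 arrays each in the groups Tconv, purTGFb_iTreg (purified TGFβ1) and pltTGFb_iTreg (platelet lysate), and the series' design text calls them biological replicates. Total RNA was extracted with Trizol, per the labels' protocols.

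The authors deposited log2 expression values, which had been summarised with Robust Multichip Analysis (RMA) in Affymetrix Expression Console, per the series' design text. RMA corrects background, quantile normalizes the arrays and fits 1 value per probe set, so values near background are compressed and small folds of dim genes are understated. Per the same text, the authors tested with ANOVA and false discovery rates in Partek Genomics Suite 6.6 and kept probe sets with a 1.4-fold difference from Tconv and a false discovery rate under 10%. Partek is also named in the submitters' processing notes. The deposited table holds no detection calls, so no probe set was called present or absent. The number of arrays limits the precision of every value.

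The table held 45101 probe sets. The 64 Affymetrix control probe sets were left out and 45037 were tested. Gene names came from the platform annotation, checked through gene identifiers against a RefSeq table of assembly GRCm38.p6, from which no coordinates were used. Of the probe sets tested, 34945 had 1 symbol, 932 had several and 9160 were not listed and stay unnamed here. Identifiers of 34741 were found in the RefSeq table and 0 symbols needed an update. For counts of genes, the probe set with the highest mean stood for each of 18193 genes, with cross-hybridising probe sets used only where a gene had no other. Probe sets of 1 gene were called in opposite directions for 61 genes in purified TGFβ against Tconv, 56 in platelet TGFβ against Tconv and 0 between the iTreg groups.

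The comparisons were each iTreg group against Tconv and the iTreg groups against each other. Each was a contrast of 1 limma model (limma 3.58.1 in R 4.3.3) over all 9 arrays with a mean per group and moderated variances, tested two-sided with Benjamini-Hochberg adjustment. A probe set was called changed at an adjusted p under 0.1 and an absolute log2 fold change above 0.5, the cutoffs of the authors. Intervals are at the 95% level. An exact test of 3 against 3 arrays cannot give a p under 0.1, so no such test was used. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

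There were 24 gene lists, written from general knowledge. They were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and called at an adjusted p under 0.05. The camera test asks whether a list shifts more than other genes. Lists were tested again with a correlation estimated for each and with fry, which asks whether a list's genes move on balance in one direction and does not compare them with other genes. List members without a named probe set were not analysed here. This left 25 of 27 members of the regulatory T cell signature, 21 of 22 TGFβ/SMAD targets, 11 of 13 Th2, 10 of 14 Th17, 11 of 13 naive or homing, 23 of 26 interferon, 29 of 30 cell cycle and 17 of 20 glycolysis genes. It also left 16 of 20 cholesterol, 12 of 14 NRF2, 18 of 20 platelet, 5 of 10 erythroid, 12 of 13 B cell, 15 of 16 myeloid, 7 of 8 CD8 or NK and 11 of 13 pan T genes. The other lists were complete. Some genes belong to several lists, such as Ifng, Dapl1 and Tnfrsf9.

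Genes were named by a rule. It took the 10 largest rises and 10 largest falls per comparison among changed genes whose arrays did not overlap, leaving out predicted and clone names. It also took up to 4 members of each list with the lowest adjusted p, and Foxp3, Il2ra, Ctla4, Itgae, Smad7, Tgfb1, Pf4 and Ppbp whatever their values. A gene named for one comparison may be given in another, and sex-linked genes were listed as a check of the animals. Groups, cutoffs, tests, lists, the check of sex-linked genes, this rule and the alternatives were fixed before the data were examined.

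Alternatives were quantile normalization of the deposited values, centring array medians, leaving out the 40% of probe sets with the lowest mean, an intensity trend with robust variances, an unmoderated ANOVA contrast, array weights and a fit on only the groups compared. Others were the replicate number as a block, the mean of a gene's probe sets, 3 other cutoffs and leaving out each array in turn. Shared controls were simulated with 1000 data sets of unchanged groups.

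The fit was tested on simulated data of 45037 probe sets with 200 changed. For purified TGFβ against Tconv it recovered 65.7% of changes of 0.6, 92.5% of changes of 1 and 100% of changes of 2 on the log2 scale, with 6 false calls. For platelet TGFβ against Tconv the shares were 64.2%, 97.0% and 98.5% with 5 false calls, and between the iTreg groups 74.6%, 95.5% and 98.5% with 6 false calls. The simulated values were independent normal draws with far fewer changes than the real comparisons called. The shares therefore check the code and do not give the recovery or false calls of the real fits. No arrays were identical, and none was left out of the comparisons.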

Results

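Gene expression was measured in mouse CD4 T cells on 9 Affymetrix arrays, 3 in each of 3 groups. Tconv stands for conventional T cells, the helper lineage without regulatory function. The other 2 groups were induced regulatory T cells (iTreg), made in culture from spleen CD4 T cells that were negative for a green fluorescent reporter of Foxp3, the transcription factor that defines regulatory T cells. These cells grew for 72 hours on anti-CD3 (2.5 µg/ml) with anti-CD28 (1 µg/ml) and IL2 (100 U/ml). TGFβ, the cytokine that drives this conversion, came either as the purified protein at 5 ng/ml (purified-TGFβ iTreg) or from freeze-thaw lysates of mouse platelets (platelet-TGFβ iTreg). The labels do not settle how the Tconv cells were treated, since a treatment note shared by all 9 samples has Tconv cells receiving TGFβ1. Nor do they say whether the iTreg cultures were sorted for the reporter before RNA was taken.

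Replicate arrays agreed closely. Pearson correlations over probe sets, which are not independent replicates, were 0.994 to 0.996 among Tconv arrays, 0.997 to 0.998 among purified-TGFβ arrays and 0.996 to 0.998 among platelet-TGFβ arrays. The iTreg groups correlated with each other at 0.993 to 0.995 and with Tconv at 0.956 to 0.970. The first principal component held 79.1% of the variance and parted Tconv from all iTreg arrays. The second held 7.6% and parted the iTreg groups. The upper quartile of log2 expression was 6.59 to 6.70 on the Tconv arrays, 6.88 to 6.95 with purified TGFβ and 6.86 to 6.91 with platelet TGFβ.

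The Tconv arrays differed from all iTreg arrays in transcripts that mark the sex of the animal. Xist, the RNA that silences an X chromosome in female cells, read 10.81 ± 0.16 (SD, n = 3) in Tconv, 3.61 ± 0.21 in purified-TGFβ iTreg and 3.94 ± 0.05 in platelet-TGFβ iTreg. Eif2s3y, a gene on the Y chromosome, read 2.70 ± 0.11, 9.01 ± 0.18 and 8.95 ± 0.07 in the same order. Kdm5d and Uty, also Y-linked, were higher in iTreg too, with log2 changes of 4.79 and 2.15 for purified TGFβ against Tconv. Every Tconv array thus read as female and every iTreg array as male, so donor sex, and whatever else separated those animals, ran together with the Tconv contrasts. Between the iTreg groups none of these 4 transcripts passed the test, and their log2 differences were 0.32, -0.06, -0.32 and 0.00.

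**Figure D1:**
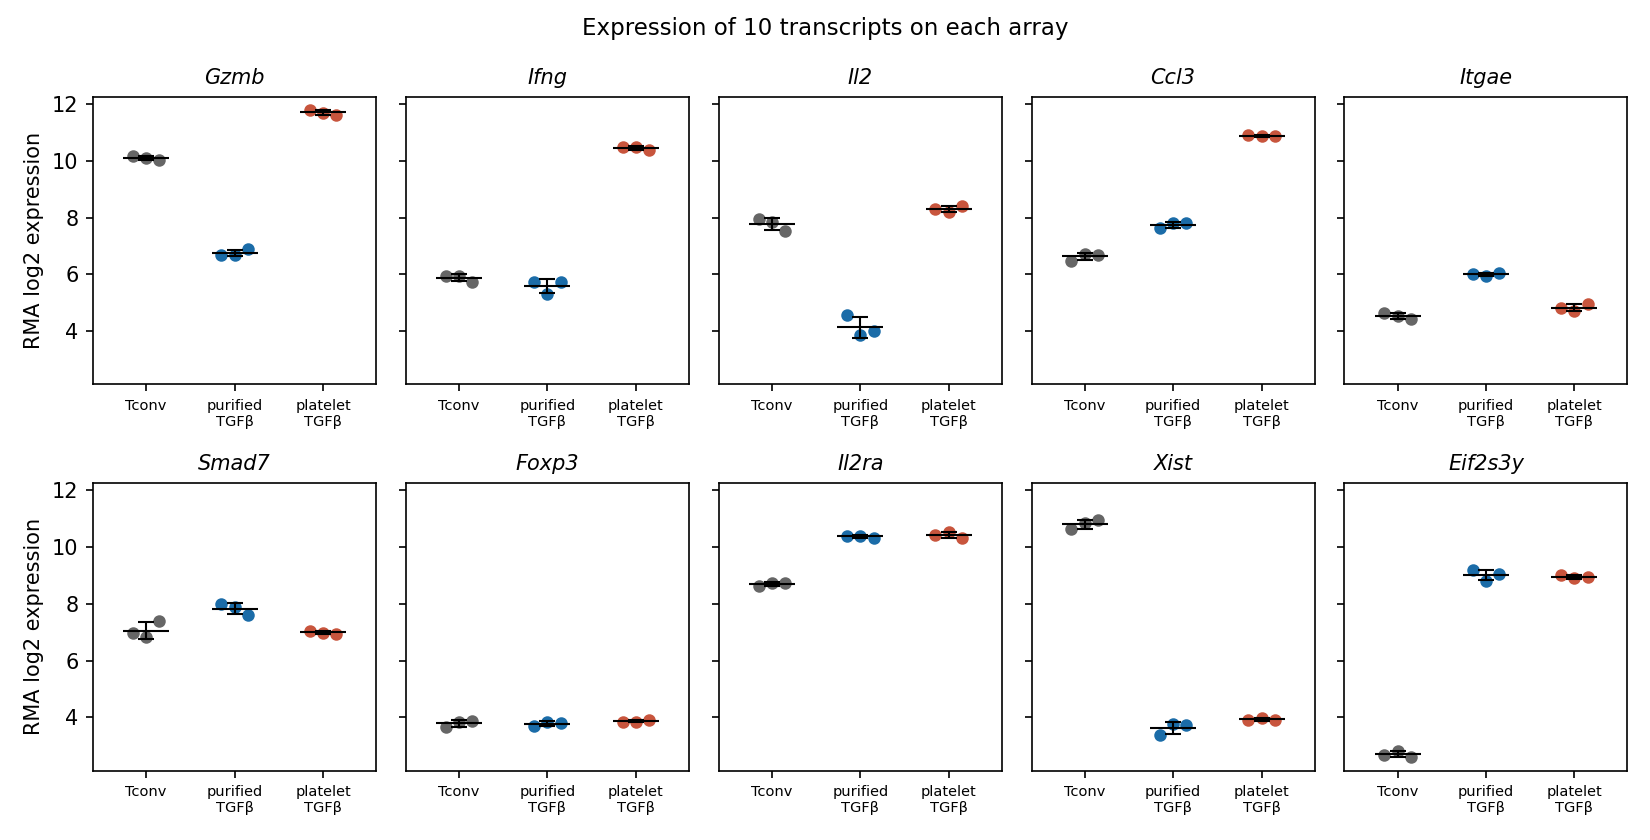
RMA log2 expression of 10 transcripts on each of the 9 arrays (points), with the mean and SD of each group of 3 (black bars). Gzmb read 10.11 in Tconv, 6.75 with purified TGFβ and 11.70 with platelet TGFβ, and Xist and Eif2s3y split Tconv from both iTreg groups.

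The comparison of purified-TGFβ iTreg with Tconv asked how cells cultured with a defined dose of TGFβ differ from conventional T cells. Several transcripts tied to regulatory T cells were far higher in the iTreg. Nt5e, which encodes the adenosine-producing ecto-enzyme CD73, rose 73.1-fold (log2 change 6.19 ± 0.08, SE, adjusted p = 2.73e-12). Another Nt5e probe set of similar brightness rose by only 2.73 on the log2 scale, and a dimmer Nt5e probe set did not pass (-0.36). Gpr83, an orphan receptor of regulatory T cells, rose 10.8-fold and the cytokine-signal inhibitor Socs2 17.7-fold. Il2ra, the high-affinity IL2 receptor chain, rose by 1.68 ± 0.08 and the inhibitory receptor Ctla4 by 1.86 ± 0.10 on the log2 scale. The integrin gene Itgae rose by 1.46 ± 0.09. Foxp3 itself read 3.79 ± 0.12 in Tconv and 3.77 ± 0.08 in the iTreg (log2 change -0.02, 95% interval -0.21 to 0.17). With no detection calls, whether its probe set read above background was not settled. The arrays thus do not show how far the cultures were converted.

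Of 25 measured members of the regulatory T cell signature, 12 rose, 6 fell and 7 did not pass (camera, adjusted p = 0.0136, higher). The adjusted p was 0.179 with an estimated correlation. The falls included Cd83, an activation marker, at 17.1-fold lower. TGFβ/SMAD targets showed 10 rises and 6 falls among 21 members (adjusted p = 0.0187, higher, and adjusted p = 0.179 with an estimated correlation). Tgfbr1, which encodes the type I TGFβ receptor, rose 18.2-fold. Skil, an inhibitor of SMAD proteins, rose 8.24-fold, the repressor Klf10 7.20-fold and Pmepa1, a feedback inhibitor of TGFβ signaling, 4.95-fold. Smad7, the inhibitory SMAD, rose by 0.77 ± 0.14. Tgfb1 fell by 1.03 on the log2 scale.

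Genes of naive T cells and lymphoid homing were higher as a list, with 6 of 11 members up and 2 down (adjusted p = 0.0148, and adjusted p = 0.179 with an estimated correlation). Klf2, which controls T cell trafficking, rose 8.16-fold, the kinase gene Txk 4.59-fold and the sphingosine phosphate receptor gene S1pr1 3.13-fold, while Dapl1 was 3.79-fold lower. IL2/STAT5 targets had 6 rises and 2 falls among 13 (adjusted p = 0.0171, and adjusted p = 0.502 with an estimated correlation). They included Bcl2, a survival factor, at 3.46-fold and the cytokine gene Lta at 3.13-fold. Cell cycle genes had 9 rises and 1 fall among 29 (adjusted p = 0.0148, and adjusted p = 0.502 with an estimated correlation), led by Ccne2 at 6.22-fold, Kif11 at 4.43-fold and the proliferation marker Mki67 at 3.36-fold. Targets of the aryl hydrocarbon receptor rose in 3 of 5 members (adjusted p = 0.0187, and adjusted p = 0.179 with an estimated correlation). Cyp1a1 rose 5.25-fold and Tiparp 2.30-fold, and Ahr, the receptor gene, rose by 5.56 on the log2 scale from a Tconv reading of 3.49. The other, dimmer Ahr probe set did not pass (0.30).

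The amino acid response run by the transcription factor ATF4 moved the other way. It had 15 falls and no rise among 18 members (adjusted p = 7.43e-06, lower), with an adjusted p of 0.179 with an estimated correlation. Cth, an enzyme of cysteine synthesis, fell by 3.46 on the log2 scale. Asns, which makes asparagine, was 4.29-fold lower, Ddit3 3.79-fold and Trib3 3.32-fold.

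Effector genes went both ways and no list of them passed. In the Th1/cytotoxic list 7 of 21 rose and 7 fell (adjusted p = 0.886). Gzmb, which encodes the protease granzyme B, was 10.2-fold lower and Stat4 3.92-fold lower, while Il18r1 rose 7.86-fold and the chemokine receptor gene Cxcr3 3.50-fold. Il2 was 12.4-fold lower within the list of genes that regulatory T cells repress, where 1 of 9 rose and 4 fell (adjusted p = 0.886). Igfbp4 rose 11.4-fold in that list. Th2 genes had 2 rises and 5 falls among 11 (adjusted p = 0.479). The cytokine gene Il4 was 8.24-fold lower and Gata3, the Th2 master regulator, 5.91-fold lower, but Maf rose 89.5-fold. Dimmer Maf probe sets rose by 2.33 to 4.21 on the log2 scale, and another did not pass (0.47). Th17 genes had 4 rises and 1 fall among 10 (adjusted p = 0.210), with log2 changes of 3.64 for Ccr6 and 3.58 for Ccl20. Follicular helper genes had 1 rise and 4 falls among 12 (adjusted p = 0.886), and Cd200 was 3.27-fold lower. Early genes of T cell receptor signaling had 1 rise and 7 falls among 16 (adjusted p = 0.136), and Egr1, Dusp2, Nr4a2 and Nr4a1 were 2.95-, 2.89-, 2.57- and 2.41-fold lower.

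The largest single rises, beside Maf, Nt5e and Ahr, given above, and Y-linked Eif2s3y, were Sgk1, a salt-sensitive kinase gene (112-fold), Cd24a (73.5-fold), Pfn2 (68.0-fold), Emp1 (63.0-fold), Ctla2b (41.7-fold) and Rragd (37.8-fold). Tconv read 3.68 for Cyp1a1, 3.66 for Maf, 3.84 for Pfn2, 3.43 for Emp1, 2.88 for Ctla2b and 3.90 for Rragd. Il18r1, given above, read about as low in Tconv as Rragd. With no detection calls, whether these were background, and the folds therefore compressed, was not settled, and the order of the rises was not tested. Beside Xist and Cd83, given above, the largest falls were Tg (42.5-fold), Crabp2 (29.2-fold), Ptpn5 (17.9-fold), Evl (16.7-fold), Stc2 (16.0-fold), Cst7 (13.8-fold), Cavin3 (13.1-fold) and Gsn (12.9-fold). Markers of other cells did not pass as lists. Platelet genes had no rise and 3 falls among 18 (adjusted p = 0.103), among them Itgb3 at 8.08-fold lower, and the platelet chemokine genes Pf4 and Ppbp changed by -0.27 and -0.30 without passing.

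In all, 11640 of 45037 probe sets differed (limma, adjusted p under 0.1 and absolute log2 change above 0.5), 6967 higher and 4673 lower in the iTreg. With 1 probe set per gene, 5339 of 18193 genes differed, 2632 higher and 2707 lower. Quantile normalization moved that split to 2262 higher and 3591 lower, a share of 38.6% higher against 49.3%. The split also turned with the fold cutoff: 32.8% of the genes called were higher with none (3785 higher, 7757 lower) and 69.7% at 2-fold and an adjusted p under 0.05 (1416 and 617). For probe sets it was 59.9% at the cutoffs used, 39.6% with no fold cutoff (9879 higher, 15077 lower) and 78.8% at 2-fold (3653 and 984). All of these differences carried the sex difference of the arrays with them. Leaving out the dimmest 40% of probe sets ended every list call but that of the ATF4 response, with an adjusted p of 0.160 for aryl hydrocarbon receptor targets and 0.0778 for the rest.

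The comparison of platelet-TGFβ iTreg with Tconv asked the same of cells cultured with platelet lysate. Many of the genes named above moved the same way: Nt5e rose 38.5-fold, Gpr83 8.67-fold, Socs2 14.8-fold, Il2ra by 1.73 ± 0.08 and Ctla4 by 2.36 ± 0.10 on the log2 scale. The second Nt5e probe set rose by only 1.85 on that scale, and the third did not pass (-0.49). Ifng, Ccl3, Ccl4 and Gzmb also stood above Tconv. Ifng, which encodes interferon gamma, rose 23.8-fold (log2 change 4.57 ± 0.12, SE, adjusted p = 3.83e-10). The chemokine genes Ccl3 and Ccl4 rose 19.0-fold and 8.16-fold, and Gzmb rose by 1.60 ± 0.09 on the log2 scale. Foxp3 changed by 0.07 (95% interval -0.12 to 0.25) and Itgae by 0.29 ± 0.09, and neither passed, but a second Itgae probe set was called higher at 0.54.

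The Th1/cytotoxic list had 12 rises and 4 falls among 21 members (adjusted p = 7.24e-05, higher, and adjusted p = 0.115 with an estimated correlation). Il18r1 was among the rises at 9.93-fold. The regulatory T cell signature had 12 rises and 5 falls among 25 (adjusted p = 0.00259, higher, and adjusted p = 0.108 with an estimated correlation), and the costimulator gene Icos rose 4.22-fold. The list of genes repressed in regulatory T cells was higher too, with 6 rises and 2 falls among 9 (adjusted p = 0.0465, and adjusted p = 0.169 with an estimated correlation). Ifng and Igfbp4 (6.10-fold) led its rises, and Satb1 (3.02-fold lower) and Dapl1 (2.36-fold lower) were its falls. That call was lost under quantile normalization (adjusted p = 0.0598) and with centred array medians (0.0703), and without Tconv replicate 1 (0.0663) or 3 (0.0541).

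IL2/STAT5 targets had 6 rises and no fall among 13 (adjusted p = 1.80e-04, and adjusted p = 0.169 with an estimated correlation), with Bcl2 at 3.65-fold and Lta at 3.60-fold. Naive and homing genes had 7 rises and 2 falls among 11 (adjusted p = 0.00399, and adjusted p = 0.108 with an estimated correlation), with Txk at 3.37-fold, Klf2 at 3.16-fold and Bach2 at 2.78-fold. Aryl hydrocarbon receptor targets rose in 3 of 5 members (adjusted p = 0.00399, and adjusted p = 0.108 with an estimated correlation), and Cyp1a1 rose 5.35-fold. The ATF4 response had 17 falls and no rise among 18 (adjusted p = 1.78e-08, lower, and adjusted p = 0.108 with an estimated correlation). Cth was 11.6-fold lower, Asns 7.10-fold, Trib3 6.10-fold and Ddit3 4.95-fold. Without the dimmest 40% of probe sets the aryl hydrocarbon receptor list and the list of repressed genes no longer passed (adjusted p = 0.0764 and 0.124).

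TGFβ/SMAD targets did not pass against Tconv here, with 6 rises and 4 falls among 21 (adjusted p = 0.163). Tgfbr1 rose 13.5-fold, Skil 6.08-fold, Klf10 4.68-fold and Pmepa1 3.35-fold, Smad7 changed by -0.06 ± 0.14 without passing and Tgfb1 fell by 1.12 on the log2 scale. The other Smad7 probe set, which can cross-hybridise, was called higher at 0.55. Th2 genes had 2 rises and 5 falls among 11 (adjusted p = 0.558), with Maf at 34.9-fold higher and Il4 at 5.61-fold lower. Dimmer Maf probe sets rose by 0.81 to 2.54 on the log2 scale, and another did not pass (0.06). Th17 genes had 3 rises and 1 fall among 10 (adjusted p = 0.107), with Ccl20 at 20.8-fold and Ahr at 19.6-fold higher. The other Ahr probe set did not pass (0.04). Follicular helper genes had 3 rises and 1 fall among 12 (adjusted p = 0.792), and Sh2d1a, the adaptor of SLAM receptors, rose 3.99-fold. Early T cell receptor genes had 3 rises and 4 falls among 16 (adjusted p = 0.0883), with Cd69 at 2.08-fold higher and Egr1 at 2.33-fold lower. Cell cycle genes had 10 rises and 2 falls among 29 (adjusted p = 0.0792), and cholesterol synthesis genes 1 rise and 9 falls among 16 (adjusted p = 0.0818), with Pmvk at 4.15-fold lower. Platelet genes had no rise and 4 falls among 18 (adjusted p = 0.113), and Pf4 and Ppbp changed by -0.02 and -0.05 without passing.

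Beside Nt5e, Maf and Ifng, given above, and Y-linked Eif2s3y and Kdm5d, the largest rises were Cd24a (71.0-fold), Sgk1 (49.9-fold), Pfn2 (35.0-fold), Rragd (23.5-fold) and Dgkh (20.8-fold). The same limit on Tconv readings holds for Pfn2, Rragd, Maf, Ahr, Cyp1a1, Il18r1 and Dgkh (3.97 in Tconv), and the order of the rises was not tested. Beside Xist and Cth, given above, the largest falls were Slc7a3, an arginine transporter gene (20.6-fold), Stc2 (17.1-fold), Ptpn5 (13.3-fold), Tg (10.6-fold), Cavin3 (8.84-fold), Ifitm2 (8.55-fold), Prxl2a (8.19-fold) and Pck2 (8.13-fold). In all, 11377 probe sets differed from Tconv, 6744 higher and 4633 lower. With 1 probe set per gene 5194 differed, 2521 higher and 2673 lower, a share of 48.5% higher that quantile normalization moved to 38.4% (2180 higher, 3497 lower). It was 33.4% with no fold cutoff (3670 higher, 7326 lower) and 69.7% at 2-fold and an adjusted p under 0.05 (1281 and 558). For probe sets the shares were 59.3%, then 40.7% (9748 and 14198) and 79.2% (3407 and 897). The sex difference between the Tconv and iTreg arrays applied to these counts as well.

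Set side by side, the iTreg groups shared most of their distance from Tconv. Of the genes that differed, 2239 were higher in both and 2032 lower in both, which is 80.0% of the purified-TGFβ calls and 82.2% of the platelet-TGFβ calls. Independent lists of these sizes would share 365 and 398. Another 1052 genes passed with purified TGFβ alone, 907 with platelet TGFβ alone and 16 in opposite directions. Across the 18193 genes, which are not independent replicates, log2 changes correlated at r = 0.931 (rho = 0.894) and 89.7% had the same sign. Simulated unchanged groups set against shared simulated Tconv arrays gave a mean r of 0.500 and 66.7% of the same sign. They shared at most 1 gene, but they held no changed genes, so that count cannot show how much shared controls add. The covariance was 0.416 against a simulated mean of 0.0065 and maximum of 0.0069. These values argue against independent noise in the shared controls as the main source of the covariance. The simulation held only such noise, so whatever set the Tconv arrays apart as a group was not in it. The 3 Tconv arrays cannot be split into parts of at least 2 for a check on separate controls. Any sex difference was shared as well.

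**Figure D2:**
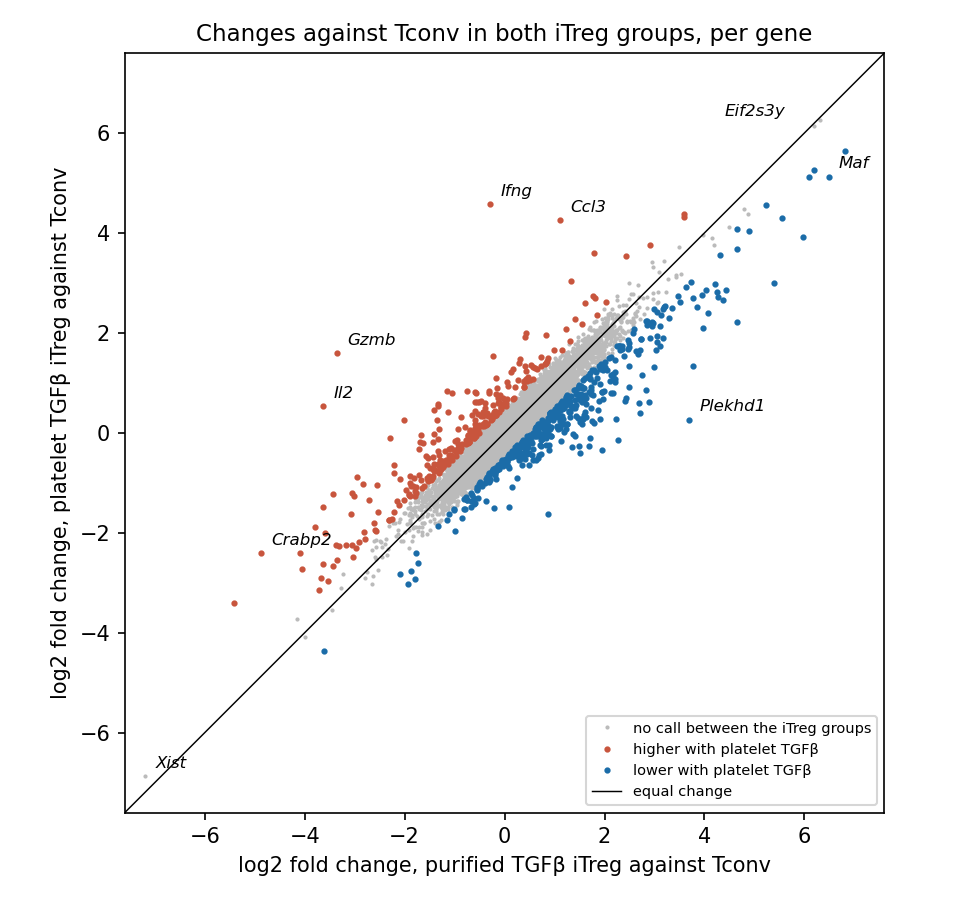
Log2 fold change against Tconv of each of 18193 genes with purified TGFβ (horizontal) and platelet TGFβ (vertical), coloured by the direct test between the iTreg groups, with the line of equal change. Most genes lie near the line (r = 0.931), while Gzmb, Ifng, Il2 and Ccl3 lie far above it.

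The direct comparison of platelet-TGFβ with purified-TGFβ iTreg asked whether the source of TGFβ mattered. The TGFβ1 concentration reached with the lysate is not given in the sources used here, so dose, source and other contents of the lysate ran together in every difference between these groups. Gzmb, Ifng, Il2, Ccl3 and Fasl were higher with platelet lysate. Gzmb read 11.70 ± 0.09 (SD, n = 3) against 6.75 ± 0.12, a 31.0-fold difference (log2 change 4.95 ± 0.09, SE, adjusted p = 2.16e-10). Ifng was 29.2-fold higher (4.87 ± 0.12, adjusted p = 3.30e-09), Il2 17.9-fold (4.17 ± 0.17, adjusted p = 1.32e-07) and Ccl3 8.80-fold (3.14 ± 0.09, adjusted p = 1.11e-08). Fasl, which encodes the death ligand, was 4.78-fold higher.

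In the Th1/cytotoxic list 9 of 21 members were higher and 1 lower (adjusted p = 3.26e-15, and adjusted p = 0.0157 with an estimated correlation). Early genes of T cell receptor signaling were higher in 10 of 16 and lower in none (adjusted p = 2.84e-15, and adjusted p = 0.0157 with an estimated correlation). Tnfrsf9, the costimulatory receptor 4-1BB, was 3.67-fold higher, the nuclear receptor gene Nr4a2 3.06-fold and the NF-κB gene Rel 1.82-fold. Genes repressed in regulatory T cells were higher in 7 of 9 and lower in 1 (adjusted p = 9.07e-09, and adjusted p = 0.0157 with an estimated correlation). Il2 and Ifng belong to that list, Dapl1 was 1.60-fold higher and Igfbp4 1.88-fold lower. Interferon response genes were higher in 4 of 23 and lower in none (adjusted p = 7.01e-04, and adjusted p = 0.0466 with an estimated correlation). The RNA sensor gene Ifih1 was 2.39-fold higher and Usp18 2.04-fold.

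TGFβ/SMAD targets were lower as a list with platelet lysate, with 1 rise and 5 falls among 21 members (adjusted p = 1.92e-04, and adjusted p = 0.0416 with an estimated correlation). Itgae was 2.26-fold lower (log2 change -1.18 ± 0.09, adjusted p = 1.17e-05) and Smad7 1.77-fold lower (-0.83 ± 0.14, adjusted p = 0.00481). Smurf1, a ubiquitin ligase that acts on SMAD proteins, was 1.67-fold lower and Klf10 1.54-fold, while Id2 was 1.62-fold higher. Tgfb1 did not pass (-0.08 ± 0.22). Cholesterol synthesis genes were lower in 5 of 16 and higher in none (adjusted p = 5.09e-11, and adjusted p = 0.0157 with an estimated correlation). Fdps was 1.63-fold lower and Nsdhl 1.52-fold. With the mean of all its probe sets Fdps changed by -0.33, under the fold cutoff. The ATF4 response was lower in 6 of 18 and higher in none (adjusted p = 8.14e-07), but its adjusted p was 0.0617 with an estimated correlation. Chac1, Trib3, Ddit4 and Asns were 1.85-, 1.84-, 1.74- and 1.66-fold lower.

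The regulatory T cell signature did not differ as a list, with 7 members higher and 7 lower among 25 (adjusted p = 0.649). Nt5e fell by 0.92 on the log2 scale and Itgae was lower as above, while Cd83 was 3.24-fold higher. Il2ra changed by 0.04 (95% interval -0.14 to 0.22) and Foxp3 by 0.08 (-0.11 to 0.27). Ctla4 was higher by 0.51 ± 0.10 on the log2 scale, just past the cutoff, and did not pass without purified-TGFβ replicate 2 (0.45) or platelet-TGFβ replicate 1 (0.49) or 3 (0.50).

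The call of each of 3 other lists was lost with an estimated correlation. Follicular helper genes were higher in 3 of 12 and lower in 1 (adjusted p = 0.00419, and adjusted p = 0.0541 with an estimated correlation), with Sh2d1a at 2.98-fold and Cd200 at 2.61-fold. IL2/STAT5 targets had 1 rise and no fall among 13 (adjusted p = 0.00294, and adjusted p = 0.251 with an estimated correlation), and Ccnd2 was 1.49-fold higher. Pan T cell genes passed at 0.0437 with no member changed, and with an adjusted p of 0.507 with an estimated correlation. That last call was also lost with centred medians (0.0530) and without purified-TGFβ replicate 1 (0.105) or platelet-TGFβ replicate 1 (0.0812) or 2 (0.0744).

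Th2 genes had 1 rise and 2 falls among 11 (adjusted p = 0.128), with Maf at 2.57-fold lower. Th17 genes had 1 rise and 3 falls among 10 (adjusted p = 0.813), with Ahr at 2.41-fold lower, though its other probe set did not pass (-0.26). Naive and homing genes had 3 rises and 1 fall among 11 (adjusted p = 0.828), with Klf2 at 2.58-fold lower. Cell cycle genes had no member changed among 29 (adjusted p = 0.0643). Among markers of other cells, platelet genes had 1 rise among 18 (adjusted p = 0.368). That gene was Itgb3, an integrin chain, at 3.36-fold higher. It stayed below Tconv with purified and with platelet TGFβ (log2 changes of -3.01 and -1.27), and its other probe set did not pass (0.26). Pf4 and Ppbp both changed by 0.25 without passing. CD8 T and NK cell genes had 2 rises among 7 (adjusted p = 0.148), Cd160 at 2.33-fold and the chemokine gene Xcl1 at 1.80-fold, while Klrk1 changed by 0.30 and Ncr1 by -0.22 without passing.

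Other large rises with platelet lysate were Crabp2 (5.51-fold), Lad1 (a log2 change of 2.20), Nrn1 (4.51-fold), Plk2 (4.48-fold) and Gpr183 (4.19-fold). The largest falls were Plekhd1 (10.8-fold), Fnbp1l (5.40-fold), Aqp3 (5.38-fold), Igha (5.27-fold), Ctla2b (5.21-fold), Camk2n1 (4.96-fold), Tph1, the first enzyme of serotonin synthesis (4.87-fold), Ndrg4 (4.80-fold), Cd40 (4.25-fold) and Emp1 (4.16-fold). Plekhd1 and Tph1 read 3.55 and 3.31 with platelet lysate, so their folds are open to the same limit. In all, 1464 probe sets differed between the iTreg groups, 523 higher and 941 lower with platelet lysate. With 1 probe set per gene 748 differed, 281 higher and 467 lower. Of the 281 higher genes, 177 had been lower with purified TGFβ than in Tconv and 88 stood above Tconv with platelet lysate. Of the 467 lower genes, 318 had been higher with purified TGFβ than in Tconv and 93 stood below Tconv with platelet lysate. Independent lists of these sizes would share 42, 39, 68 and 69 in the same order. These comparisons share iTreg arrays, so part of the excess may come from that. Simulated unchanged groups shared at most 2 genes, but they held no changed genes, so that count cannot show how much shared arrays add.

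Across the 24 lists, the counts adjusted over the list alone were the same as those adjusted over all probe sets, in every list and comparison. With an estimated correlation between genes, 6 of the 10 list calls between the iTreg groups held and none of the 7 in either comparison with Tconv. Those 6 were the Th1/cytotoxic, early T cell receptor, repressed, interferon, TGFβ/SMAD and cholesterol lists. For some lists that did not pass, the median, mean and test differed in sign. With purified TGFβ against Tconv these were the Th1/cytotoxic, Th17 and CD8 or NK lists. With platelet TGFβ against Tconv they were the TGFβ/SMAD, follicular helper, interferon, cell cycle, glycolysis and CD8 or NK lists. Between the iTreg groups they were the regulatory T cell, Th17, naive, myeloid and CD8 or NK lists.

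**Figure D3:**
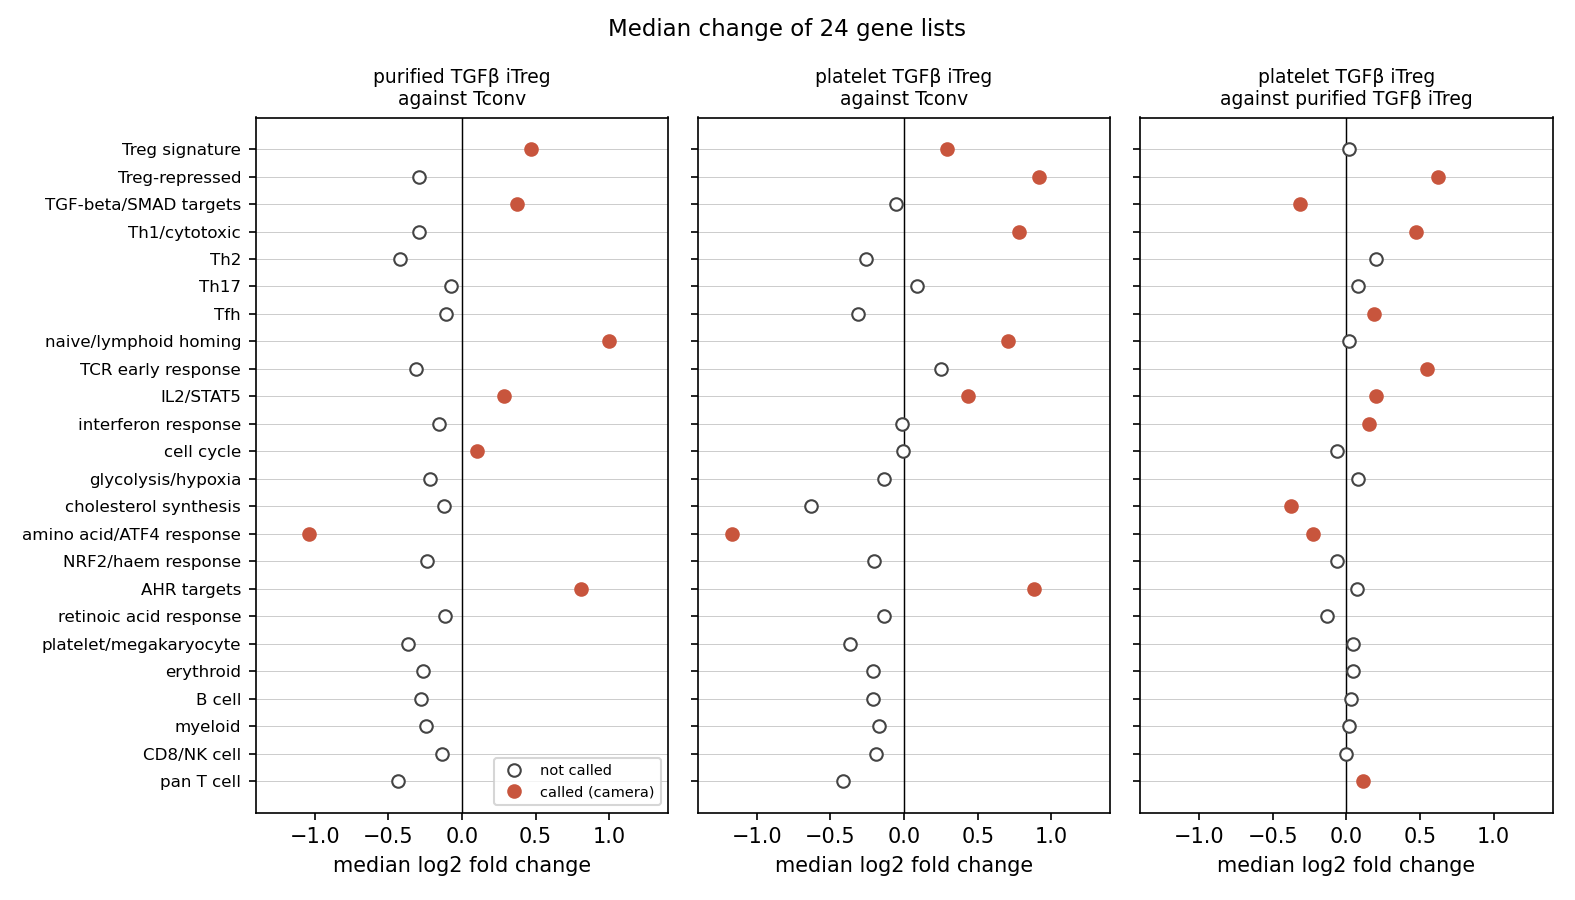
Median log2 fold change of the measured members of 24 gene lists in the 3 comparisons, with lists that passed the camera test at an adjusted p under 0.05 filled. The Th1/cytotoxic list has a median of -0.29 with purified TGFβ and 0.78 with platelet TGFβ against Tconv.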

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

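Every test of an explanation in this part, on sex-linked genes, CD8 T and NK cell markers (both sets), SMAD targets, effector genes and other splits of the arrays, was chosen only after the result it bears on was seen.

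Gzmb, Il2 and Tnfrsf9 stood out because they moved in opposite directions against Tconv in the iTreg groups. The direct contrast is the difference of those changes, so for genes picked this way it is no separate evidence. Gzmb changed by -3.36 with purified TGFβ and 1.60 with platelet TGFβ, a difference of 4.95. Il2 changed by -3.63 and 0.54, a difference of 4.17, and Tnfrsf9 changed by -1.34 and 0.54, a difference of 1.88, but another Tnfrsf9 probe set changed by 0.30 with platelet TGFβ and was not called. Both rises of 0.54 were just past the cutoff: that of Il2 was lost without Tconv replicate 3 (0.41) or platelet-TGFβ replicate 3 (0.48), and that of Tnfrsf9 without Tconv replicate 3 (0.47) or platelet-TGFβ replicate 1 (0.49) or 2 (0.48).

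The effector transcripts that were higher with platelet lysate, Gzmb, Ifng, Il2, Ccl3 and Fasl, were weighed against 3 explanations. Donor sex is argued against, since the iTreg groups differed in Xist, Eif2s3y, Kdm5d and Uty by at most 6.73% of the gap between Tconv and purified-TGFβ iTreg. CD8 T or NK cells that escaped CD4 isolation and the sort stay open: Cd8a, Cd8b1, Ncr1, Klrk1 and Klre1 had a median difference of -0.0641, but these leave out Cd160 and Xcl1, which rose by 1.22 and 0.84, and with them the median of all 7 was -0.0018 over members that went both ways. A weaker TGFβ response, from a lower dose or from the source, may be part of the pattern, since SMAD targets were lower as a list with platelet lysate (adjusted p = 0.0416 with an estimated correlation). Whether it could also account for the effector part cannot be told apart from other effects of the lysate, because 6 of the 9 higher Th1/cytotoxic genes also stood above Tconv, and Tconv differed in sex and has an unsettled TGFβ treatment.

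Xist and the Y-linked genes split the Tconv arrays from the iTreg arrays. As a check for one mislabelled or swapped array, 0 arrays were out of place on any of these genes. That count restates the split itself, so it is no separate test. All iTreg arrays read as male, so a swap between the iTreg groups could not show here. Donor sex, or another difference in preparation that followed the groups, cannot be told apart from iTreg culture in either comparison with Tconv. The gap in Xist between the lowest Tconv and highest iTreg array was 6.64 on the log2 scale. No comparison within one sex could therefore be made. How much of those differences is biological was not tested.

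Other splits of the 6 arrays in each comparison into 3 and 3 were too few for a share under 0.05, and 1 of 10, the real one, gave as many probe sets. The real split gave 11640 for purified TGFβ against Tconv, 11377 for platelet TGFβ against Tconv and 1464 between the iTreg groups, and the highest other split gave 0 in each.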

How the results depend on the processing

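All alternatives were planned. With no fold cutoff, purified TGFβ against Tconv, platelet TGFβ against Tconv and platelet against purified TGFβ gave 24956, 23946 and 3286 probe sets, or 11542, 10996 and 1768 genes, with 9453 genes shared by both comparisons with Tconv. At an adjusted p under 0.05 and 2-fold they gave 4637, 4304 and 294 probe sets, or 2033, 1839 and 169 genes, with 1548 shared. Both follow from the cutoff itself. Without the dimmest probe sets 1 list passed for purified TGFβ against Tconv, and the cause was not tested. An estimated correlation left 0, 0 and 6 lists. It was above the preset of 0.01 for some lists, such as the ATF4 response (0.135). For the regulatory T cell signature it was -0.0039, under the preset. The p of that list with purified TGFβ against Tconv still rose from 0.00113 to 0.0110 (camera). A higher correlation thus cannot account for that loss, and what did was not tested. The fry test, which asks another question, called 22 and 23 in the comparisons with Tconv. Ighm turned from 0.82 and 0.65 to -0.12 and -0.10 against Tconv with the mean of its probe sets and was not called then. Leaving out each array in turn gave 11040 to 12546, 11211 to 12077 and 1388 to 1481 probe sets, 5082 to 5764, 5166 to 5475 and 720 to 754 genes, 4119 to 4494 shared genes, and 7 to 7, 6 to 9 and 9 to 10 lists. With the replicate number as a block there were 11643, 11381 and 1464 probe sets and 5339, 5194 and 745 genes, and the lists called stayed at 7, 7 and 10. Only 2 of 9 same-number pairs correlated above 0.1 (-0.123 to 0.262). Between the iTreg groups these were 0.194, 0.262 and 0.0919, and every iTreg array correlated best with its own number there, a hint from the data and not from the design. Counted per named gene, comparison and setting, leaving out an array left 3072 results on their side of the cutoffs, lost 15 calls and added 18, and the other alternatives left 3968, lost 91, added 44 and reversed 2. Vegfa between the iTreg groups lost its call with quantile normalization, array weights and the ANOVA contrast and without purified-TGFβ replicate 3 (-0.47) or platelet-TGFβ replicate 3 (-0.38). Another, dimmer Vegfa probe set was called lower at -0.73. Medians centred gave 56.5% and 55.3% of changed genes higher than Tconv. RMA compresses folds near background, and with no detection calls the probe sets this limits were not settled.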

Other observations

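The share of larger shifts among genes that also differed between the iTreg groups was the only test in this part chosen after its result was seen.

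Metabolic and stress genes that the comparisons did not lead with went both ways. Cholesterol synthesis genes had 2 rises and 7 falls among 16 with purified TGFβ against Tconv (adjusted p = 0.886), where Pmvk fell by 1.66 and Lss by 1.23 on the log2 scale while Sc5d rose by 1.03. Glycolysis and hypoxia genes had 3 rises and 4 falls among 17 with purified TGFβ (adjusted p = 0.895) and 3 rises and 5 falls with platelet TGFβ (adjusted p = 0.584). The hypoxia-inducible genes Bnip3 and Egln3 rose by 1.92 and 1.56, and by 2.09 and 1.71, while the glycolytic enzyme gene Aldoa fell by 0.65 and 0.58. Between the iTreg groups that list had 1 rise and 1 fall (adjusted p = 0.178), with Hk2 higher by 0.68. NRF2 and haem response genes had 3 falls among 12 with purified TGFβ (adjusted p = 0.612), 1 rise and 4 falls with platelet TGFβ (adjusted p = 0.504) and no change between the iTreg groups (adjusted p = 0.649). Blvrb, which encodes biliverdin reductase B, fell by 1.53 and 1.63. Retinoic acid response genes had 1 fall among 8 against Tconv in each group, Stra6, which fell by 0.78 and 0.71 (adjusted p of the list 0.895 and 0.510), and none between the iTreg groups (adjusted p = 0.389). Aryl hydrocarbon receptor targets did not differ between the iTreg groups (adjusted p = 0.592). Interferon response genes had 3 rises and 9 falls among 23 with purified TGFβ against Tconv (adjusted p = 0.886) and 3 rises and 4 falls with platelet TGFβ (adjusted p = 0.504). Ifit2 rose by 1.48 and 1.66, while Usp18 fell by 1.53 with purified TGFβ.

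Markers of other cells did not pass as lists against Tconv. Pan T cell genes had 5 falls among 11 with purified TGFβ (adjusted p = 0.161) and 2 rises and 4 falls with platelet TGFβ (adjusted p = 0.239), and the kinase gene Zap70 fell by 1.15 and 1.03. CD8 T and NK cell genes had 1 rise and 2 falls among 7 (adjusted p = 0.886), then 1 rise and 1 fall (adjusted p = 0.947), with Xcl1 higher by 2.91 and 3.75 and Cd8b1 lower at -0.98 and -1.04. B cell genes had 1 rise and 2 falls among 12 in both (adjusted p = 0.458 and 0.504), and Cd79b fell by 1.46 and 1.65. Myeloid genes had 1 rise among 15 (adjusted p = 0.688), then 1 rise and 1 fall (adjusted p = 0.558), with Mpeg1 higher by 1.15 and 0.64. Erythroid genes had 1 fall among 5 in both (adjusted p = 0.442 and 0.504). That gene was Klf1, at -0.56 and -0.64, and the first did not pass without purified-TGFβ replicate 3 (-0.49). Between the iTreg groups no member of the B cell or erythroid list changed (adjusted p = 0.649 each). Igha and Cd40 are not on the B cell list, and both were lower with platelet lysate (-2.40 and -2.09). Whether those falls reflect B cells was not tested. Myeloid genes had 1 fall (adjusted p = 0.649), Mpeg1 at -0.51. Mpeg1 did not pass without purified-TGFβ replicate 2 (-0.48), platelet-TGFβ replicate 1 (-0.48) or 3 (-0.49).

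Of the 16 genes called in opposite directions against Tconv, some fall outside the naming rule and were chosen after their values were seen. Gadd45g and Gadd45b, growth arrest genes induced by stress and cytokines, were higher with platelet than with purified TGFβ by 1.86 and 1.41. Tnfsf4, which encodes the costimulatory ligand OX40L, was higher by 1.60. Tsc22d3, a glucocorticoid-induced gene, was lower at -1.18.

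One hypothesis was that platelet lysate gave a weaker form of the same response throughout. Its test was written before the test value was seen. By then a slope of 0.859 of platelet on purified changes was known, fitted only on genes called with purified TGFβ against Tconv. It asked for at least 75% of the genes changed the same way in both comparisons to have the larger shift with purified TGFβ, and 53.1% did (2270 of 4271). That does not exclude it, because any change that followed the sex or preparation of the Tconv arrays would be shared by both groups and pull the share towards equality, which the limit set for the test did not allow for. The share was 55.0% among 2239 higher genes and 51.1% among 2032 lower genes, and the median absolute shift was 0.94 with purified and 0.91 with platelet TGFβ. Of the 333 of these genes that also differed between the iTreg groups, 269 (80.8%) had the larger shift with purified TGFβ and 64 with platelet TGFβ. This selection leaves out genes that platelet TGFβ moved past Tconv. As plain counts over all genes that differed, the platelet mean lay between Tconv and purified TGFβ for 142 of 281 higher genes (50.5%). For lower genes the count was 271 of 467 (58.0%). The platelet mean lay beyond Tconv for 81 higher (28.8%) and 123 lower genes (26.3%). For 58 higher (20.6%) and 73 lower genes (15.6%) Tconv lay on the other side of purified TGFβ, so the platelet shift was the larger. These positions rest on the same Tconv arrays and share their limits. A weaker response is possible for the genes in between. The larger platelet shifts go against it for those genes, within the same limits, and for the genes beyond Tconv the question stays open.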
